A study of Mus musculus with 11 samples.

How the data were processed

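Chromatin isolation by RNA purification followed by sequencing (ChIRP-seq) was used on HPC5 cells, a mouse hematopoietic progenitor line derived from bone marrow. In this assay biotinylated DNA oligonucleotides complementary to an RNA are hybridized to cross-linked, sonicated chromatin, and the genomic DNA recovered with the RNA on streptavidin beads is sequenced. Per the labels' protocols, glutaraldehyde at 1% fixed the cells for 10 minutes, glycine ended the reaction, and the chromatin was sheared by sonication to 200 to 500 bp. The series holds 11 libraries. 6 are pull-downs with probes to the long non-coding RNA LncHSC-2: 2 with the complete set of 12 probes, 2 with its 6 odd-numbered probes and 2 with its 6 even-numbered probes. 2 are pull-downs with 6 probes to LacZ, a bacterial gene with no counterpart in mouse cells, and 3 are input chromatin. The complete-set libraries are 2 biological replicates, per the labels, while each of the odd, even and LacZ pairs consists of technical replicates of 1 biological replicate.

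The analysis used 2 deposited peak lists in narrowPeak layout, a format of 10 columns with no header: a consensus list for the LncHSC-2 pull-downs and a list for the LacZ pull-downs. The submitters' processing notes name Bowtie2 2.0.6, MACS2 2.0.10.20131216 and the genome build mm9, with no role or settings. The last LacZ peak on chromosome 1 ends at position 195719463. The labels give the consensus list for all 6 LncHSC-2 libraries, but how the libraries were combined is not given in the sources used here, nor is whether regions found with LacZ probes were removed. The names of the consensus peaks carry the run names that the labels give to the 2 complete-set libraries, and peaks were assigned to those replicates by name. The labels give the LacZ list for both LacZ libraries, so it is 1 list over both. The deposited fold enrichment is, per the column order of the files, the caller's ratio of the pull-down signal at the peak summit to the local background. As recovered below, 1 is added to both, so the fold lies below the plain ratio, most strongly at low background, and depends on depth. The deposited −log10 p-values and −log10 q-values are likewise those of the authors' caller. The folds and significance values themselves were used only to describe, rank or filter peaks within their own list, because the libraries were called at different depths; the fragments and backgrounds recovered from them were also compared between lists. Per-library coverage was not analysed here, so the comparisons are between lists of peaks, and no p-value measures the spread between libraries.

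Sequencing depth is not stated in the labels. It was recovered in relative terms from the peaks themselves. For each peak the whole number of fragments n at the summit and the local background λ were sought that give both deposited values, the fold as (n + 1)/(λ + 1) and the p-value as the Poisson probability of more than n fragments. A solution within 0.0001 of the deposited −log10 p was found for 220 of 220 and 44 of 44 consensus peaks and for 5502 of 5504 LacZ peaks. The exceptions are 2 of the highest LacZ peaks. The calculation could not evaluate probabilities as small as theirs, so the largest whole number within its reach was kept. For these 2 peaks the fragments are a lower limit. For 1 LacZ peak a second whole number also met the tolerance. The lowest λ in a list is the caller's genome-wide background and is proportional to the number of fragments times their length. It was 0.364 for replicate 1 and 0.455 for replicate 2 of the complete set, and 0.0868 for LacZ, so the LacZ list was called at a background 4.20 times below that of replicate 1 and 5.24 times below that of replicate 2.

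Positions are 1-based in mm9. Overlap and proximity were tested by random placement: each consensus peak kept its width and chromosome and was placed uniformly over the span of the 2 lists on that chromosome, 10000 times, with a two-sided p. An overlap was at least 1 bp, and distances were measured from edge to edge. The distribution over chromosomes was compared with a chi-square statistic and 100000 Monte Carlo permutations of list membership, followed by Fisher's exact test per chromosome with Benjamini-Hochberg adjustment. Median widths were compared with a two-sided permutation test (100000 permutations). Shares carry 95% Wilson intervals, and a count of 0 is given with the share that 3 counts would make; both cover counting error only. Tests were run with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were checked on simulated lists of 264 peaks. The overlap test called 20 of 20 lists with 5 planted shared peaks and 0 of 20 without, and the clustering test called 20 of 20 lists with up to 20 planted neighbours and 1 of 20 without. The chromosome test called 20 of 20 lists with 1 chromosome raised by a factor of 3 and 0 of 20 unchanged lists, and the width test called 20 of 20 lists with widths raised by 40 bp and 0 of 20 unchanged lists. Whole fragments were recovered for 489 of 489 simulated peaks. These were made with the formulas that the recovery assumes, so this checked the calculation and not the formulas. The simulated peaks did not reach the highest fragment numbers and backgrounds of the lists.

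The peaks named were chosen by a rule fixed before the data were examined: the 10 consensus peaks and the 5 LacZ peaks with the highest fold enrichment, every consensus peak overlapping a LacZ peak, and the densest window of 100000 bp in each list. The tests and most alternatives were fixed at the same time. Alternatives covered the definition of overlap and proximity, stricter thresholds for either list, local placement within 1000000 bp, autosomes alone and merging of neighbouring peaks; leaving out the peaks named after each replicate, LacZ peaks of at least 4 fragments and widths at equal fragment numbers were added after seeing the data. Gene context, sequence motifs and lists of genes near the peaks were planned but not run, because no genome or annotation of build mm9 was used here; peaks are therefore given by position without a gene, exon or intron. A planned comparison of fold enrichment between LacZ peaks with and without an overlapping consensus peak was not run because no LacZ peak was overlapped.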

Results

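LncHSC-2 is a long non-coding RNA studied in hematopoietic stem cells, and its sites on chromatin were mapped by ChIRP-seq in HPC5 cells, a mouse bone marrow progenitor line. The pull-downs with LncHSC-2 probes are represented by 1 consensus list of 264 peaks, and the pull-downs with LacZ probes by a list of 5504 peaks. The LacZ probes are a control for recovery that does not depend on the sequence of the probes. They cannot show recovery of other targets by the LncHSC-2 probes, and their set holds 6 probes against 12 in the complete set. Both lists cover the same 20 chromosomes, 1 to 19 and X. Of the consensus peaks, 220 (83.3%) carried the name of biological replicate 1 of the complete probe set and 44 (16.7%) that of replicate 2. The fold enrichments and q-values below are those of the authors' caller, and each belongs to the single library or list that named the peak.

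The lists differed in depth and in selection. At most 1.84% of the numbered peaks of replicate 1 and 0.643% of those of replicate 2 stand in the consensus list under their own names. The LacZ list holds 100% of its numbered peaks. The fragment numbers below therefore set a selected list against one without such selection. LncHSC-2 consensus peaks rested on a median of 11 fragments at the summit (interquartile range 9 to 17, lowest 4), and 245 of the 264 (92.8%, 95% Wilson interval 89.0 to 95.3%) held at least 7. LacZ peaks rested on a median of 3 fragments (interquartile range 3 to 5), and 2829 of the 5504 (51.4%, 50.1 to 52.7%) held exactly 3, the lowest number in that list. At least 7 fragments were found in 583 LacZ peaks (10.6%, 9.81 to 11.4%). The background per position was 0.364 fragments in replicate 1, 0.455 in replicate 2 and 0.0868 in the LacZ pull-down, so a site equally enriched in all of them would hold fewer fragments in LacZ by a factor of 4.20 to 5.24.

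**Figure D1:**
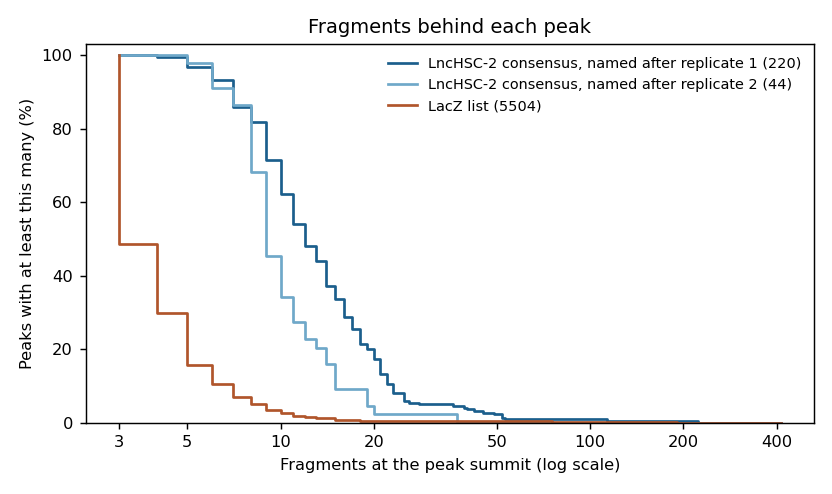
Share of peaks (%) with at least the number of fragments on the x axis (log scale), as step lines for the consensus peaks named after each complete-set replicate and for the LacZ list. The LacZ line falls to 48.6% at 4 fragments, while 92.8% of all consensus peaks hold at least 7. The consensus list is a selected part of its libraries' peaks, and the LacZ list is not.

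The first question was where LncHSC-2 probes recovered chromatin. The highest of the 264 sites was on chromosome 3 at 142679905 to 142680726, with a fold enrichment of 69.4 over local background, −log10 q of 202 and 113 fragments at its summit. Its fold was 1.79 times that of the next site, on chromosome 10 at 70703198 to 70704328, which had a fold of 38.9 and 52 fragments. The third, on chromosome 6 at 134609247 to 134609901, had a fold of 34.6 and 49 fragments. A site on chromosome 19 at 3708025 to 3708402 followed with a fold of 29.4, and a site on chromosome 2 at 165111926 to 165112310 with a fold of 28.0. The remaining named sites lay on chromosome 17 at 26852386 to 26852680 with a fold of 25.8, on chromosome 10 at 84379703 to 84380429 with 25.1 and at 76992897 to 76993177 with 24.7, and on chromosome 1 at 36748146 to 36748460 with 22.1 and at 194621176 to 194621718 with 21.3. All 10 were named after replicate 1, and each held between 28 and 113 fragments. The highest site named after replicate 2, chosen after its value was seen, was on the X chromosome at 46307659 to 46307901, with a fold of 13.0 and 19 fragments.

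Over the whole consensus list the median fold was 8.31 (interquartile range 6.55 to 11.7). It was 8.99 among the sites named after replicate 1 and 6.83 among those named after replicate 2; these folds come from separate libraries and were not tested against each other. The least significant consensus peak had a q-value of 0.0303.

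LacZ probes gave their highest fold on chromosome 5 at 47743257 to 47743673, with a fold of 20.2 from 22 fragments. A site on chromosome 10 at 120802009 to 120802370 had a fold of 18.4 from 19 fragments. The third, on chromosome 17 at 39982220 to 39983413, differed from these in depth: its 144 fragments stood over a local background of 6.97, for a fold of 18.2. Sites on chromosome 11 at 11586002 to 11586251 and on chromosome 4 at 9576600 to 9576887 had folds of 17.2 and 16.8, each from 18 fragments. The median LacZ fold was 3.68. Folds of the 2 lists were called against different backgrounds and are given side by side without a test.

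The second comparison asked whether LncHSC-2 sites were also recovered with the control probes. None of the 264 LncHSC-2 peaks shared a base with any of the 5504 LacZ peaks (0%, and a count of 0 of 264 allows up to 1.14%). Random placement of the same peaks gave 0.323 overlaps on average, with the central 95% between 0 and 2, so the observed 0 did not differ from chance placement (random placement permutation test, two-sided p = 1). The test could have shown an excess of shared sites but not a deficit. The nearest approach was on chromosome 10, where the LncHSC-2 peak at 42358419 to 42359009, with a fold of 9.53, began 23 bp past a LacZ peak of 4 fragments at 42358226 to 42358395.

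Next in distance was a LncHSC-2 peak on chromosome 17 at 39984948 to 39985773, which lay 1534 bp from the LacZ site of 144 fragments on that chromosome. It held 222 fragments, the most of any consensus peak, over a local background of 28.8, the highest in the list, for a fold of 7.49.

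LacZ peaks lay within 10000 bp of 17 LncHSC-2 peaks (6.44%, 95% Wilson interval 4.06 to 10.1%), against 11.2 expected by random placement (central 95% of 5 to 18, two-sided permutation p = 0.113). The count did not exceed the spread of random placement. With LacZ peaks limited to the 1316 with −log10 q of at least 5, 7 LncHSC-2 peaks lay within this distance against 2.68 expected (two-sided permutation p = 0.041, not adjusted for the other settings tried). The median distance to the nearest LacZ peak was 135020 bp.

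**Figure D2:**
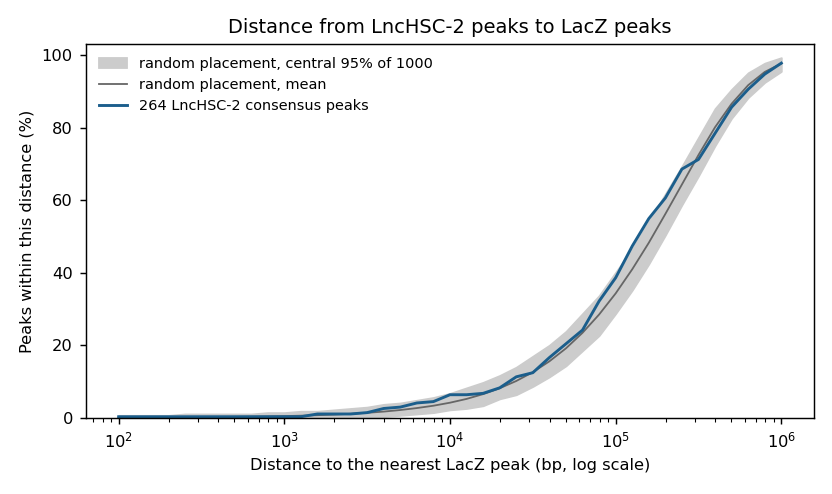
Share of the 264 LncHSC-2 consensus peaks (%) with a LacZ peak within the distance on the x axis (bp, log scale), with the mean and central 95% of 1000 random placements. The observed line lies within the central 95% at 10000 bp (6.44%) and 100000 bp (38.6%), and above it at 125893 bp (47.3% against an upper limit of 46.6%) and 158489 bp (54.9% against 54.2%).

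The third comparison was the distribution over chromosomes. LncHSC-2 and LacZ peaks were spread over the 20 chromosomes without a detectable difference (chi-square 20.6, Monte Carlo permutation p = 0.359). Chromosome 13 held 18 LncHSC-2 peaks (6.82%, 95% Wilson interval 4.36 to 10.5%) against 220 LacZ peaks (4.00%, 3.51 to 4.55%), an odds ratio of 1.76 with Fisher's exact p = 0.0371 and an adjusted p of 0.609 over the 20 chromosomes. The X chromosome held 22 LncHSC-2 peaks (8.33%, 5.57 to 12.3%) against 306 LacZ peaks (5.56%, 4.98 to 6.20%), with Fisher's exact p = 0.0748 and an adjusted p of 0.609. Chromosome 12 went the other way, with 6 LncHSC-2 peaks (2.27%, 1.05 to 4.87%) against 252 LacZ peaks (4.58%, 4.06 to 5.16%; Fisher's exact p = 0.0914, adjusted p = 0.609). No chromosome passed an adjusted threshold of 0.05, and 1 passed it unadjusted.

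**Figure D3:**
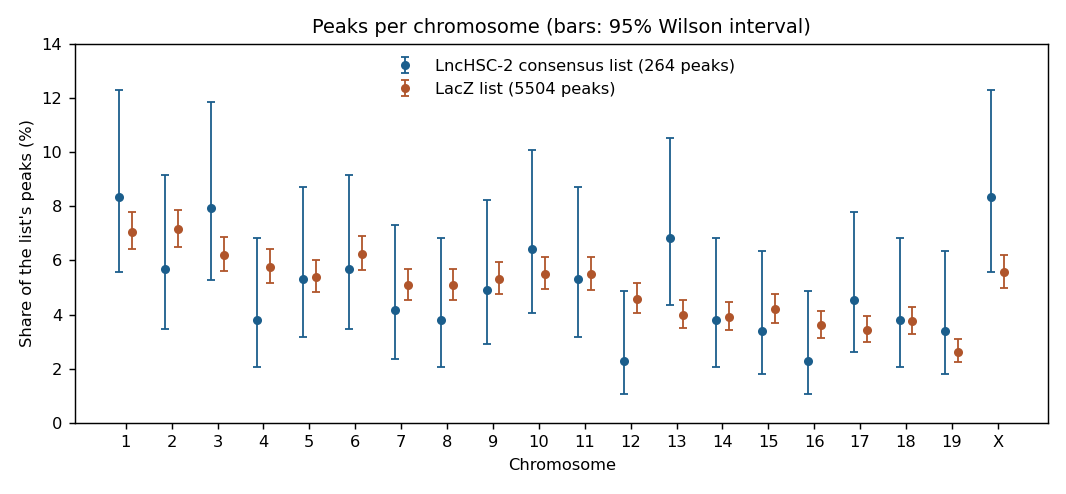
Share of each list's peaks (%) on each chromosome, with 95% Wilson intervals, for the LncHSC-2 consensus list and the LacZ list. Chromosome 13 lies at 6.82% against 4.00% and the X chromosome at 8.33% against 5.56%.

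The fourth comparison concerned spacing. LncHSC-2 sites were mostly isolated: 4 of the 264 (1.52%) had another LncHSC-2 peak within 100000 bp, against 5.43 expected by random placement (central 95% of 0 to 12, two-sided permutation p = 0.971). These 4 formed 2 pairs. One joined the highest site on chromosome 3 to a peak 22590 bp away, at 142703317 to 142703924, with a fold of 6.37 and 9 fragments. The other, on chromosome 1, joined peaks at 74553327 to 74553796 and 74585150 to 74585378, which had folds of 7.62 and 7.17. Further neighbours lay just past this distance. Another peak on chromosome 3, at 142808615 to 142808979 with a fold of 13.7, lay 104690 bp beyond the 6.37-fold member, and peaks on the X chromosome at 166508438 to 166508996 and 166612340 to 166613043 lay 103343 bp apart. LacZ peaks were closer together than random placement gave, with 2086 (37.9%) within 100000 bp of another against 1939 expected (central 95% of 1856 to 2022, 1000 placements, two-sided permutation p = 0.002, the smallest these placements can give). Placement made no allowance for stretches where no peak can be called, which could also make real peaks look closer. That was not tested. The densest LacZ window was on chromosome 9 at 3000112 to 3064515 and held 23 peaks. Among them were peaks of 317 and 313 fragments and the highest in the list by fragments, with at least 414. That number is a lower limit, since larger numbers were beyond the reach of the calculation. No window of that size held more than 2 LncHSC-2 peaks.

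**Figure D4:**
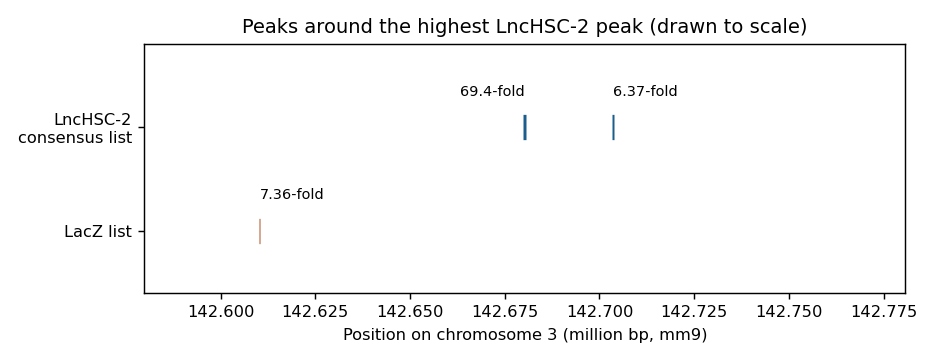
Peaks of both lists on chromosome 3 within 100000 bp of the highest LncHSC-2 site, drawn to scale by position (Mb, mm9), with their folds. The LncHSC-2 peaks of 69.4-fold and 6.37-fold lie 22590 bp apart.

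LncHSC-2 peaks were also wider than LacZ peaks, with a median of 283.5 bp (interquartile range 232.75 to 374.75) against 203 bp (181 to 281). The difference of 80.5 bp was larger than any from reassigned list membership (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). For peaks of equal fragment number, from 5 to 18, the difference of medians was taken at each number and averaged, weighted by LncHSC-2 peaks. It was 36.4 bp (212 LncHSC-2 and 1606 LacZ peaks, p = 0.0003 by 10000 permutations within each number). At 13 fragments the LncHSC-2 median was the smaller, with 281.5 against 291 bp, and at every other number it was the larger. The 44 peaks named after replicate 2 alone had a median of 225 bp, 22 bp above LacZ, which did not pass the threshold (permutation p = 0.0657). The narrowest peaks were 187 bp for replicate 1, 169 bp for replicate 2 and 170 bp for LacZ. Neither comparison of widths was adjusted for this or for the selection of peaks into the consensus list.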

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

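All tests in this part except the count of LacZ peaks around the site were chosen after the result was seen. Peak names carry a running number along the genome, so the numbers of neighbouring consensus peaks show how many peaks of the same library lay between them without entering the consensus list. Between the highest LncHSC-2 site on chromosome 3 and its neighbour 22.6 kb away, 2 further peaks of complete-set replicate 1 were called, where its average rate gives 0.106 and the LacZ list holds 0. An exact Poisson test gave p = 0.00524 (adjusted p = 0.0105 over the 2 pairs of neighbours), while the pair on chromosome 1 had 0 peaks between its members. The stretch was picked because it joins close consensus peaks at the highest site, and the rate was taken as even along the genome. The p-value allows for neither that choice nor an uneven peak density, so no excess can be concluded from it. These peaks lie outside the consensus list, and the comparisons between the LncHSC-2 and LacZ lists did not use them.

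For the pair of consensus peaks itself, chance spacing stays open; another consensus peak, 104690 bp past the pair, lies beyond the distance tested. A consensus peak fell as near to the single highest site in a share of 0.0071 of random placements, and as near to any of the 10 highest sites in a share of 0.0527, which lies close to the threshold of 0.05; the wider set was chosen after the first share was seen, because the site was not singled out in advance. A local rise of background stays open too: 4 LacZ peaks lay within 1000000 bp of the site against 4.42 expected at the average rate of the chromosome, a count too small to show a rise at the scale of the pair. A further hypothesis, recovery of the gene that LncHSC-2 is transcribed from, which probes to an RNA may pull down directly, was not tested, since the position of that gene in mm9 was not used here.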

How the results depend on the processing

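The settings that leave out the peaks of a replicate, use LacZ peaks of at least 4 fragments or match fragment numbers were chosen after seeing the data. Of 33 alternatives with a test, 28 kept the direction and the side of the 0.05 threshold. This count is no measure of stability, because several of them could not have changed. These were most overlap settings, the direction of every chi-square, and the merging of consensus peaks for clustering, where none lay within 10000 bp of another. The median fragments and median fold, which have no test, moved by less than 1 SD of the peaks without either replicate. The overlap with LacZ peaks was 0 under each of its 7 alternatives and with either replicate's peaks left out (0.0457 to 0.367 overlaps by random placement). Most of these had to give 0, since stricter rules, subsets and local placement cannot add an overlap to lists that share no base. Only the rule of summits within 200 bp could have differed. The number of LncHSC-2 peaks near a LacZ peak passed the threshold only with LacZ peaks of −log10 q of at least 5 (7 against 2.68 expected, permutation p = 0.041), while LacZ peaks of at least 4 fragments gave 10 against 5.44 expected (permutation p = 0.104); at 1000 bp the direction turned, with 1 peak against 1.45 expected. Clustering turned, with no call on either side, at 1000000 bp (51 peaks against 49.2 expected) and without the peaks named after replicate 2 (4 against 3.79 expected). Leaving out the peaks named after each replicate gave 0 to 0 overlaps, 2 to 15 peaks near a LacZ peak, 0 to 4 clustered peaks, a chi-square over chromosomes of 18.1 to 28.2 and a width difference of 22 to 96.5 bp; the width call was lost on the 44 peaks of replicate 2 alone (22 bp, permutation p = 0.0657), where both the set and the difference were smaller; the cause was not tested. The lists limit what can be said: a LacZ site was called from 3 fragments upward at a background 4.20 to 5.24 times lower than that of the LncHSC-2 libraries. The alternatives for gene context, motifs and gene lists, and those for LacZ peaks under an overlapping consensus peak, were not run. No paired analysis was possible because each consensus peak carries the values of 1 library only and the LacZ list does not separate its 2 libraries.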

Other observations

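Tests of the fragments expected in LacZ at the LncHSC-2 sites and of peak density per chromosome were set before their results were seen; those of random stacking, of removed peaks and of the 2 replicates' chromosomes came after.

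No site was shared by the LncHSC-2 and LacZ lists, whereas if each LncHSC-2 site were probe-independent background, equally strong in the LacZ pull-down, its fragments scaled to the LacZ background would have given 7.99 called LacZ peaks among the 8 sites with the most fragments, those scaled to at least 10 LacZ fragments, and 0 were seen. One of the 8 is the site of 222 fragments on chromosome 17, whose fold of 7.49 lies below the median of the list. Without it 6.99 were expected for 7 sites and 0 seen, and 6.28 at 50% of the strength (7.22 for all 8). If no regions shared with LacZ were removed before deposit, this argues against background of equal strength and of 50% strength at these sites. If they were removed, 0 overlaps were fixed in advance here as well. The number of such sites before removal is not known, so both strengths would then stay open. For the other 256 sites 129 were expected and 0 seen, but this part stays open: if regions shared with LacZ were removed before deposit, the weaker sites left over would look the same. Whether such removal took place stays open. Random placement cannot show it, since it gives only 0.323 overlaps and supposes that the lists share no background. Background below 50% of the strength stays open too, as does recovery through the RNA itself, a biological explanation the design names and no test here addresses, and the site on chromosome 17, 1534 bp from a LacZ site of 144 fragments, lies in a stretch with raised background in both lists.

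Fragment numbers can be set against chance stacking. At the LacZ background, with fragments of 170 bp (the narrowest peak in that list) scattered evenly over the 2551 Mb spanned by the peaks, chance would stack exactly 3 fragments at up to 4365 places, and 2829 such peaks were listed, so chance stacking may account for peaks of this size. It falls short for LacZ peaks of 4 or more, with 130 expected and 2675 listed, which an uneven background could give; that was not tested. For LncHSC-2 sites named after replicate 1, even scatter of fragments of 187 bp, the narrowest of these peaks, gives 11.2 places with 7 or more, and 205 of the 220 were at or above that number. An uneven background could give this excess too, and that was not tested. At lower numbers even scatter gives more places, with 184 expected and 213 listed at 6 or more and 2526 expected and 219 listed at 5 or more. These counts include the 205 sites of 7 or more, so they concern only the few sites below that number. The places are those of the whole library, of whose numbered peaks at most 1.84% stand in the consensus list under their own names. Expected and listed counts can therefore not be matched there. Even scatter alone stays open for the sites of fewer than 7 fragments.

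The numbering of peak names also shows how small a part of each library's peaks gave its name to a consensus peak. Peaks that may have entered under the name of the other replicate are not counted. The highest numbers were 11970 for replicate 1 and 6842 for replicate 2, so at most 1.84% and 0.643% of the peaks of these libraries were kept under their own names. The numbers count the peaks of replicate 1 only between its outermost consensus peaks on each chromosome, a stretch of 41.1 Mb on chromosome 12 to 161 Mb on chromosome 1. Within these stretches of the 20 chromosomes, numbered peaks of replicate 1 per Mb and LacZ peaks per Mb had Spearman rho = 0.402 (permutation p = 0.0804, adjusted 0.161) and Pearson r = 0.407 (permutation p = 0.0759, adjusted 0.152), and r = 0.684 without the 2 chromosomes farthest from the median LacZ density; chromosomes are not independent replicates. The test left open whether the replicate 1 peaks in these stretches follow the same background as LacZ. Over the full span of the 2 lists on each chromosome, and not only these stretches, consensus peaks of both replicates per Mb were compared with LacZ peaks per Mb. They had rho = 0.186 (permutation p = 0.429) and r = 0.227 (permutation p = 0.334), with r = 0.153 without the 2 farthest chromosomes. A difference over chromosomes between consensus peaks named after replicates 1 and 2 did not pass the threshold (permutation p = 0.0933); 7 of 44 lay on the X chromosome for replicate 2 and 15 of 220 for replicate 1 (Fisher's exact p = 0.0675).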
